A study of Homo sapiens with 16 samples.

How the data were processed

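LSD1 was profiled by chromatin immunoprecipitation followed by sequencing (ChIP-seq) in 4 HEK-based cell lines, with 2 replicate cultures per line and an immunoprecipitated (IP) and an Input library from each culture, 16 libraries in all. Per the series' design text, the cultures of a line were grown independently, and the Input was taken from the same chromatin as the IP. The data used here were 8 lists, each, per the labels, of an IP library called against the Input of its own culture, so replicates were not pooled. Cell line and fraction were taken from the labels, and the replicate number from the sample titles.

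The submitters' processing notes name Bowtie2 2.1.0, SICER 1.1 and the build hg19, without stating the step each was used for. Bowtie2 is an aligner, and SICER joins neighbouring windows that hold more IP reads than a random background into islands and is meant for broad signals. Per the labels, which carry the list names, the window was 200 bp, the allowed gap 1000 bp and the false discovery rate (FDR) 0.05, and the lists went through a further filter whose content is not given in the sources used here. The files bear these settings out in part: 100% of island widths were multiples of the window, the smallest gap between islands of a list was 1200 bp, and the highest FDR was 0.0500. The only measurement per island is the FDR, an adjusted p-value of IP over Input that the authors' caller gave, and 2 islands have an FDR of 0. It was used only to rank and filter islands within a list.

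The lists hold no reads, fold enrichments or library totals. Sequencing depth is therefore unknown, a region without an island can be a region with fewer reads, and lists of different length can differ in depth or in the yield of the IP. Joining windows across gaps also makes the number of islands depend on how continuous the signal is, so covered length and island width were given beside each number. A test on reads in regions called in all 4 libraries of a comparison had been planned for lists with reads and was dropped. Likewise, promoters and gene lists were not used here, since the gene table at hand belongs to another genome build than hg19; regions are given by coordinates alone, counted from 1.

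Islands of the 4 lists of a comparison were merged into regions where they shared at least 1 bp. A region was called gained where both libraries of the first line and neither of the second had an island, lost in the opposite case, and kept where all 4 had one. For each count, the libraries were also split in the 2 other ways, each side with 1 library of each line. Positional chance was taken from 1000 circular shifts (seed 1), in which replicate 2 of the line that holds the regions was moved within each chromosome. The resulting one-sided p measures whether the replicates of that line meet at the same places more often than unrelated lists, not whether lines differ. Its smallest possible value was 0.001, and Benjamini-Hochberg adjustment ran over 10 counts. Chromosome extents ran from the first to the last island in any list, 2785 Mb over 22 autosomes.

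The overlap of 2 lists was the Jaccard index, the shared bases divided by the bases in either list. It was compared with 1000 shifts along the whole chromosome and with 1000 shifts of between 100 kb and 1 Mb, which keep the broad distribution of islands, with adjustment over 28 pairs. Resemblance within lines was tested one-sided over all 105 ways to pair the 8 libraries. Numbers of islands, covered lengths and median widths were compared between the 4 libraries of Epi-HOT and Epi-HOT-dP and the 4 of Epi-CTR and Epi-HOT-dL with a two-sided exact permutation test of mean log10 values. That grouping was chosen before the data were examined but with the sizes of the lists in view, so it was not blind to the number of islands, and the test of width was added later. Intervals of shares are exact 95% binomial intervals over islands or regions, which cover counting error only.

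The regions named were chosen by a rule fixed before the data were examined: per comparison and direction, the 10 with the best of the worse of the 2 ranks by FDR in the replicates that hold them. The rule was written for reads and fell back on the FDR. The script was tested on simulated lists, in which it recovered all 200 regions planted per class in each of the 5 comparisons, and unrelated lists gave 0.878 to 1.02 times the shifted overlap. Planted sites were sparse, their widths were capped, and all copies of a site shared a base. Recovery therefore checks the counting, not the merging of dense or very wide islands. The alternatives tried were an FDR of 0.001, 50% reciprocal overlap, lists cut to equal length by FDR, islands merged within 1 kb, and each library left out in turn, all fixed before the data were examined, and a few settings added later. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.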

Results

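LSD1 (KDM1A), a histone demethylase found in chromatin repressor complexes, was mapped by ChIP-seq in 4 lines made from HEK cells, a human embryonic kidney line. HOTAIR is a long non-coding RNA known to bind LSD1 and PRC2, a histone methyltransferase complex. From background knowledge of the study, Epi-CTR is the control line, Epi-HOT expresses HOTAIR, Epi-HOT-dP expresses HOTAIR without its PRC2-interacting part and Epi-HOT-dL expresses HOTAIR without its LSD1-interacting part; the labels give the names of the lines only. Each line had 2 replicate cultures. The 8 lists held 85586 LSD1 islands, between 1116 and 20592 per library. No reads are listed, so the depth behind these numbers is unknown.

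In 6 of the 8 libraries LSD1 islands were densest on chromosome 19 or 22. Chromosome 19, which is rich in genes, carried 5.61% and 6.95% of the autosomal islands of Epi-CTR replicates 1 and 2, against 2.11% of the autosomal span. It carried between 5.44% and 6.56% in Epi-HOT replicate 1, Epi-HOT-dP replicate 2 and both Epi-HOT-dL libraries. Epi-HOT replicate 2 and Epi-HOT-dP replicate 1 were different: only 0.394% (95% interval 0.159 to 0.810) and 0.359% (0.0979 to 0.917) of their islands lay on chromosome 19, which was the sparsest autosome in both. Chromosome 13 was the densest there, with 9.35% (8.03 to 10.8) and 32.0% (29.2 to 34.8) of islands, while Epi-HOT-dP replicate 2 had 3.68% (3.28 to 4.11) and the other 5 libraries 1.99% to 2.51%. Most of these islands lay between 90 and 110 Mb of chromosome 13, a stretch that held 130 islands of Epi-HOT replicate 2 and 321 of Epi-HOT-dP replicate 1, or 7.32% and 28.8% of their autosomal islands, against 1.86% in Epi-HOT-dP replicate 2 and 0.440% to 0.914% in the others. In the same pair of libraries a stretch of 2 Mb around position 130243201 of chromosome 8 held 1.41% and 3.32% of islands, against at most 0.210% in the others. The bounds of both stretches were chosen after the positions had been seen.

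**Figure D1:**
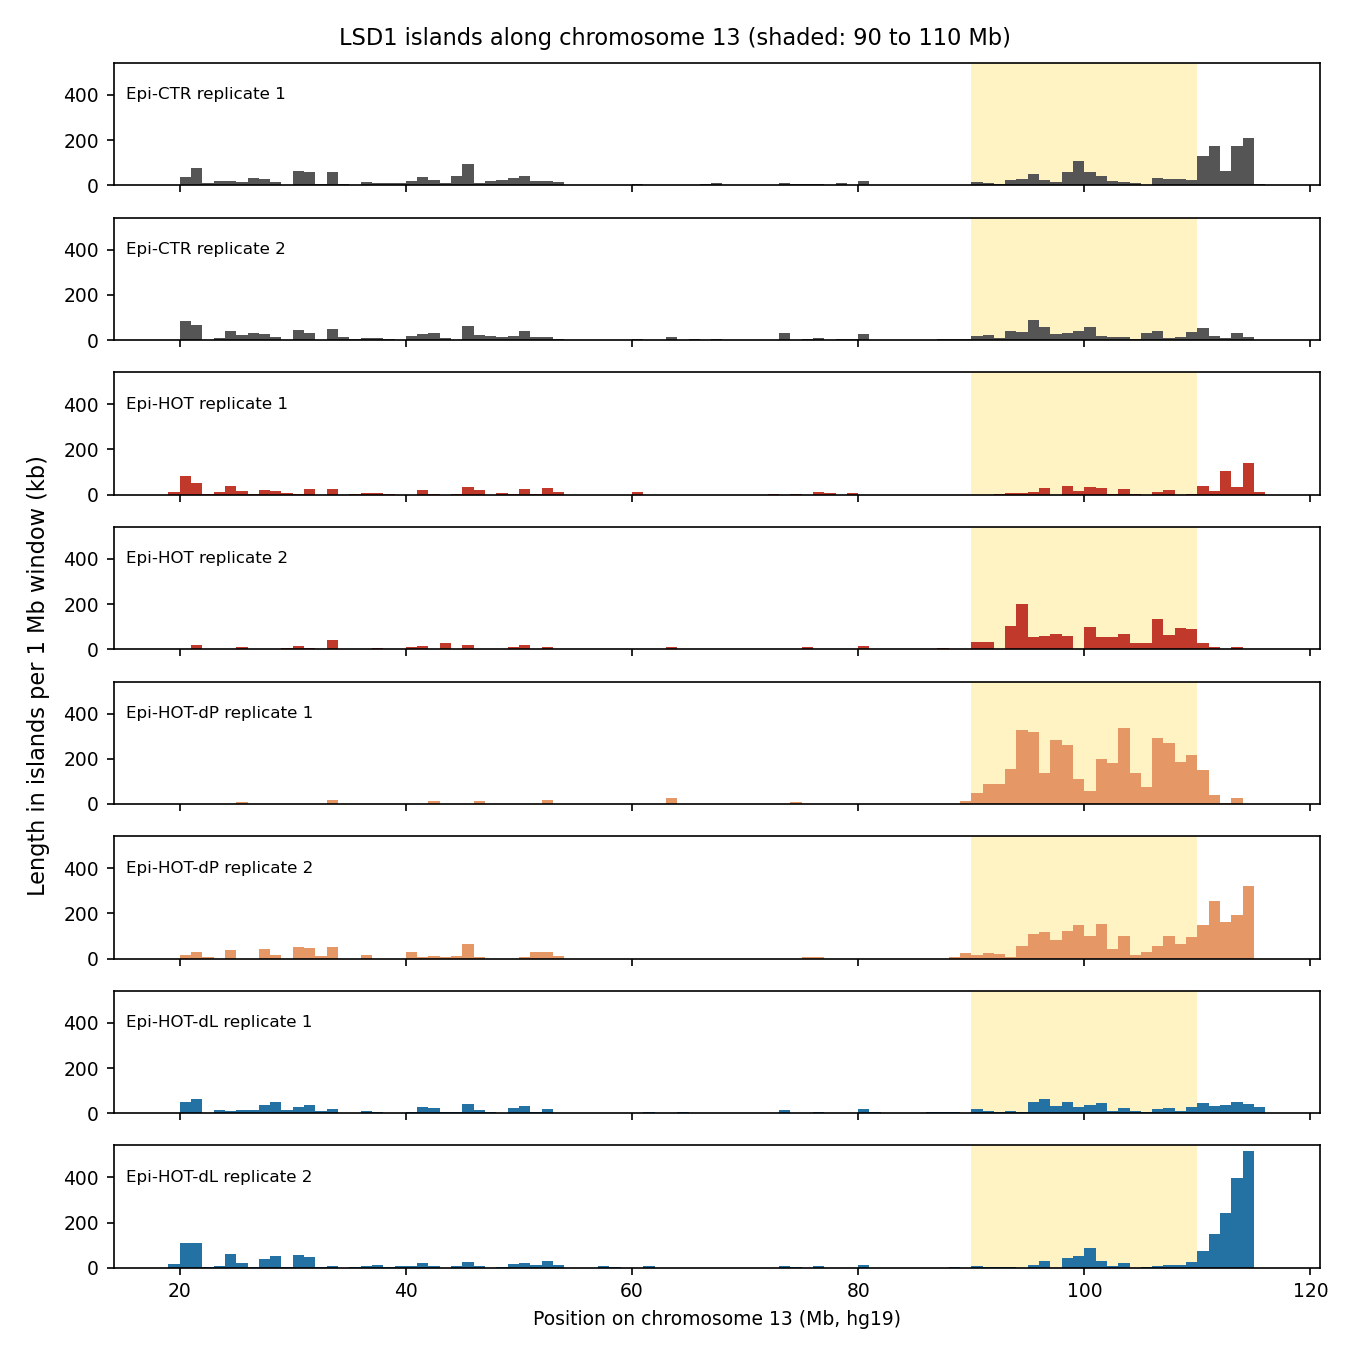
Length covered by LSD1 islands in 1 Mb windows along chromosome 13 (hg19), in kb, with a row per library and the 90 to 110 Mb stretch shaded. Epi-HOT replicate 2 and Epi-HOT-dP replicate 1 have most of their chromosome 13 islands in the shaded stretch, which held 7.32% and 28.8% of their autosomal islands.

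Few places were called in most libraries. Merging all lists gave 41795 regions, of which 24934 (59.7%) had an island in a single library, 25 in 7 libraries and 1 in all 8, at chromosome 4 from 57937801 to 57949600. Of the 25, 17 lacked an island only in Epi-HOT-dP replicate 1, among them wide stretches of chromosome 19 at 1500001 to 1627800, 4156601 to 4320400 and 18356001 to 18688800. Leaving out Epi-HOT replicate 2 and Epi-HOT-dP replicate 1, 600 regions were shared by the other 6 libraries. An island of 1.8 kb at chromosome 20 from 26188801 to 26190600 had the smallest FDR of the list in Epi-CTR replicate 1 (1.39e-187), Epi-HOT-dP replicate 2 (9.84e-21) and Epi-HOT-dL replicate 1 (5.65e-161), and an island 2 kb wide at the same place was first in Epi-HOT-dL replicate 2 (2.12e-176). By FDR it ranked 4 in Epi-CTR replicate 2, 33 in Epi-HOT replicate 1 and 103 in Epi-HOT replicate 2. Epi-HOT-dP replicate 1 had no island there.

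Libraries of the same line did not stand out among chance pairings of the libraries. The mean Jaccard index was 0.0891 within lines and 0.0758 between lines, but 22 of the 105 ways to pair the libraries gave a mean as high (exact one-sided p = 0.210). Epi-CTR replicates shared 26.9 Mb (Jaccard index 0.187), and 47.5% of the islands of replicate 2 met an island of replicate 1. The Epi-HOT-dL replicates had an index of 0.144, the Epi-HOT-dP replicates 0.0171 and the Epi-HOT replicates 0.00830. All 4 within-line overlaps exceeded shifted positions, by 8.01, 4.11, 4.19 and 2.18 times in that order, and by 4.51, 1.93, 2.18 and 2.13 times with shifts of at most 1 Mb, which keep the broad distribution of islands (permutation p = 0.001, the smallest possible, for each). Across lines the highest index was 0.214, between Epi-HOT replicate 1 and Epi-HOT-dL replicate 2, and Epi-HOT replicate 2 met Epi-HOT-dP replicate 1 with 0.0654, or 14.5 times the shifted overlap and 3.27 times that of the short shifts. Among the 15 pairs without either of these last libraries, every pair lay above the shifts, by 3.57 to 8.01 times, and by 1.93 to 4.51 times with short shifts. Epi-HOT-dL replicate 2 overlapped Epi-HOT replicate 2 and Epi-HOT-dP replicate 1 less than shifted positions did (0.712 and 0.314 times, or 0.813 and 0.388 times with short shifts).

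**Figure D2:**
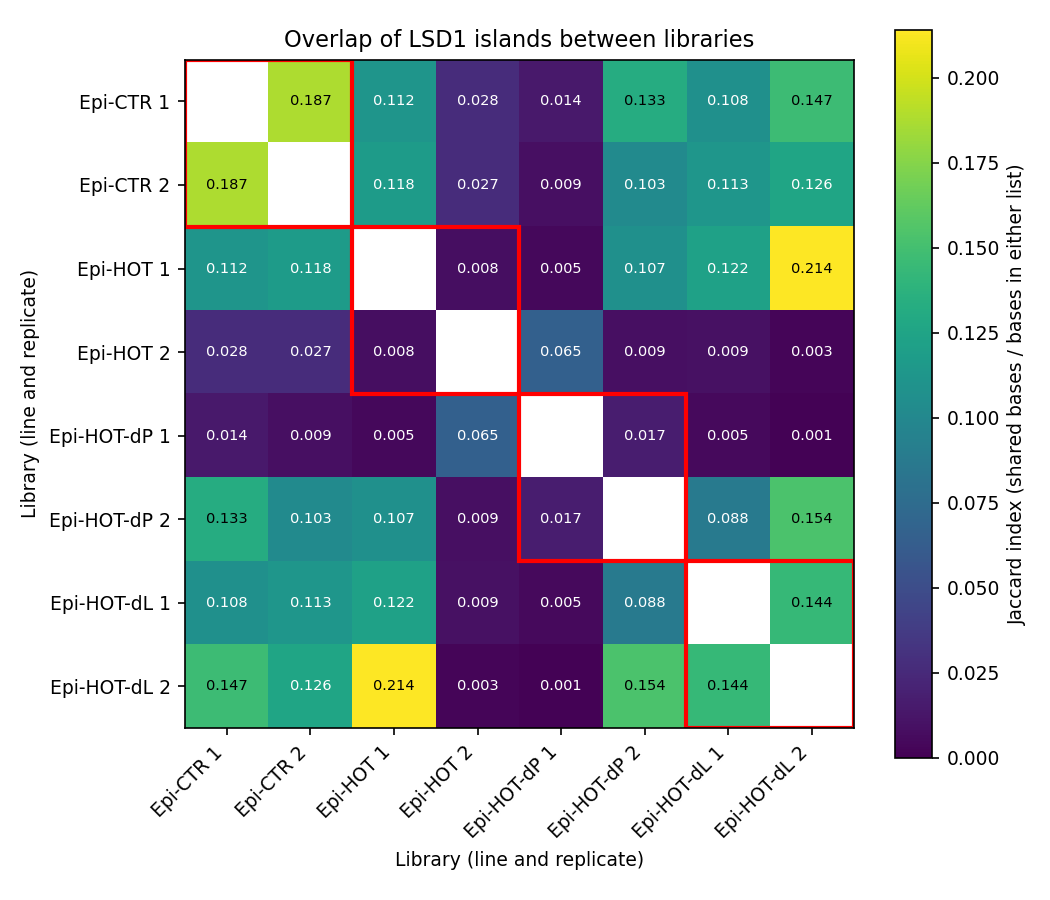
Jaccard index of shared LSD1 island bases for each pair of libraries, with lines and replicates on both axes and the pairs of a line outlined in red. The index was 0.187 between the Epi-CTR libraries and 0.00830 between the Epi-HOT libraries, and the highest, 0.214, joined Epi-HOT replicate 1 with Epi-HOT-dL replicate 2.

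The first comparison asked whether lines whose HOTAIR keeps the LSD1-interacting part differ in the number of LSD1 islands. Epi-HOT had 4167.5 ± 3379 islands (SD, n = 2) and Epi-HOT-dP 4597.5 ± 4924, while Epi-CTR had 17765 ± 3998 and Epi-HOT-dL, which lacks that part, 16263 ± 714. The 4 libraries of Epi-HOT and Epi-HOT-dP, at 1116 to 8079 islands, all lay below the 4 of Epi-CTR and Epi-HOT-dL, at 14938 to 20592. Islands in the first pair of lines were mostly wider, with a median width of 7 to 9.8 kb against 3.8 to 7.6 kb. The length covered by islands overlapped between the arms, at 12.6 to 83.9 Mb against 77.3 to 203 Mb.

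The geometric mean number of islands was 5.27 times lower where the part was kept (exact two-sided permutation p = 0.0286, the smallest that 70 regroupings allow; 0.0857 after adjustment over 3 measures). The covered length was 3.06 times lower (exact permutation p = 0.143) and the median width 1.77 times higher (exact permutation p = 0.0571, adjusted 0.0857). Replicates differed by 3.69 times in Epi-HOT and 7.24 times in Epi-HOT-dP, an FDR limit of 1e-05 lowered the difference to 2.92 times (exact permutation p = 0.143), and leaving out any library of Epi-CTR or Epi-HOT-dL left it at 4.94 to 5.49 times (exact permutation p = 0.0571 to 0.0857). It was 6.70 or 4.33 times without Epi-HOT replicate 1 or 2, 3.71 or 7.18 times without Epi-HOT-dP replicate 1 or 2, and 2.32 times without Epi-HOT replicate 2 and Epi-HOT-dP replicate 1. Libraries of a line are not separate lines, and with 2 lines against 2 an exact test cannot go below 0.333.

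**Figure D3:**
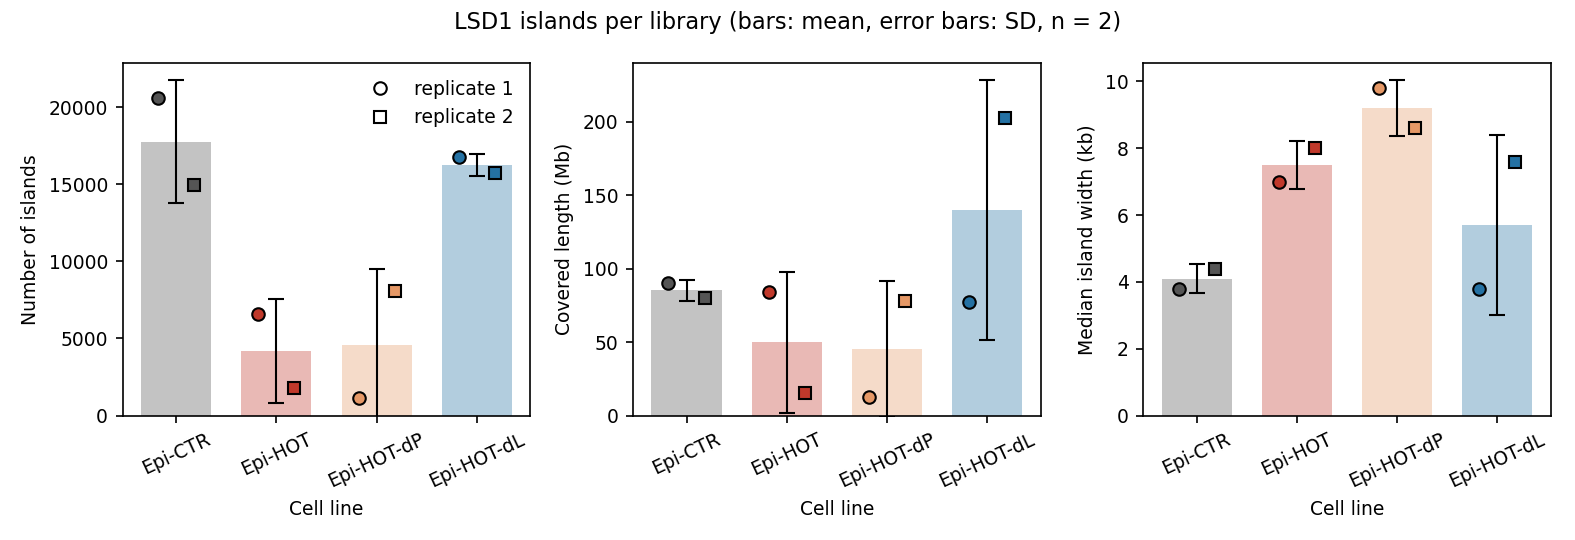
Number of LSD1 islands, covered length in Mb and median island width in kb for each line, with circles for replicate 1, squares for replicate 2, bars for the mean and error bars for the SD (n = 2; an error bar that would pass below 0 ends at the axis). The 4 libraries of Epi-HOT and Epi-HOT-dP have 1116 to 8079 islands and those of Epi-CTR and Epi-HOT-dL 14938 to 20592.

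Epi-HOT was compared with Epi-CTR to see where LSD1 sits when HOTAIR is expressed. Of 6475 regions with an island in both Epi-CTR libraries, 4485 (69.3%) had none in either Epi-HOT library, and 113 (1.75%) had one in both. Both Epi-HOT libraries held an island in only 231 regions, and 43 of these (18.6%) were gained. Lost regions had a median width of 6.4 kb and were spread over the genome, with 10.4% on chromosome 1, 6.82% on chromosome 2 and 5.31% on chromosome 19. The strongest were at chromosome 15 from 67387401 to 67404200, with FDRs of 1.15e-35 and 2.06e-19 in the Epi-CTR replicates, at chromosome 1 from 17491201 to 17504400 (3.07e-32 and 3.89e-17), and at chromosome 22 from 36817601 to 36839000 (6.24e-27 and 3.09e-16).

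A second lost region lay near the last of these, at chromosome 22 from 36936001 to 36945800. The 10 named lost regions also included chromosome 17 from 75415001 to 75428400, chromosome 9 from 114796601 to 114806800 and chromosome 10 from 100015401 to 100033400. All 10 had an island in at least 1 Epi-HOT-dL library and 7 of them in both, unlike the whole set of 4485, of which 18.9% had an island in both Epi-HOT-dL libraries and 40.8% in neither. The first gained region, at chromosome 9 from 36397201 to 36403400, had FDRs of 2.99e-10 and 9.43e-06 in the Epi-HOT replicates, and was also called in Epi-HOT-dP replicate 1. The next were at chromosome 20 from 36684201 to 36697200 and, within the 90 to 110 Mb stretch, chromosome 13 from 102066201 to 102078200. Of all 43 gained regions, 55.8% had no island in Epi-HOT-dL and 81.4% none in Epi-HOT-dP. Among all regions held by both Epi-HOT libraries in the comparisons with these lines, the shares were 33.9% of 221 and 75.1% of 225.

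Shifting 1 replicate gave 829 lost and 27.4 gained regions (permutation p = 0.001 and 0.004, adjusted 0.0011 and 0.004), and the other splits of the 4 libraries gave 194 to 1076. The lost count lay above all of these splits and the gained count below all of them. Gains are limited by how few regions the Epi-HOT replicates shared. Lists of equal length, 1778 islands each, kept the direction but left 286 lost and 65 gained regions. With Epi-CTR replicate 1 or 2 left out, 11252 or 15652 regions were lost, and with Epi-HOT replicate 1 or 2, or Epi-CTR replicate 1, left out, 774, 3163 or 94 were gained. Kept regions rose from 113 to 458 or 1637 without Epi-HOT replicate 1 or 2.

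Epi-HOT-dL was set against Epi-HOT to ask what changes when the LSD1-interacting part is missing. LSD1 islands were present at 3309 regions in both Epi-HOT-dL libraries and absent from both Epi-HOT libraries, while 75 regions changed the other way and 56 were kept. Both Epi-HOT libraries held only 221 regions here, against 4853 for both Epi-HOT-dL libraries. Of the gained regions 6.44% lay on chromosome 19. Their width came from Epi-HOT-dL replicate 2, whose islands there had a median of 12 kb, against 4.2 kb in replicate 1. The best ranked was a merged stretch of 79.2 kb at chromosome 11 from 64549001 to 64628200, with FDRs of 6.48e-08 and 3.24e-28, followed by 55.8 kb at chromosome 19 from 50346801 to 50402600 (2.39e-07 and 2.22e-29) and 3.8 kb at chromosome 5 from 153568001 to 153571800 (7.62e-09 and 2.56e-22).

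Of all 3309 gained regions, 1001 (30.3%) had an island in both Epi-CTR libraries, 32.3% in a single one and 37.5% in neither. The 10 named were richer in Epi-CTR regions, with 7 in both libraries; the region at chromosome 9 from 108554601 to 108566400 was called in the Epi-HOT-dL libraries alone. The widest of the 10, a merged stretch of 133.4 kb at chromosome 16 from 70669201 to 70802600, was called in both Epi-CTR libraries and in Epi-HOT-dP replicate 2. Lost regions were led by chromosome 13 from 104958801 to 104968400, within the stretch where Epi-HOT replicate 2 stood apart (FDRs of 6.90e-15 and 3.52e-13 in the Epi-HOT replicates), chromosome 1 from 238570001 to 238577800 and chromosome 2 from 181841601 to 181849400. Of all 75 lost regions 86.7% lacked an island in Epi-HOT-dP as well.

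Shifting 1 replicate gave 1125 gained and 22.8 lost regions (permutation p = 0.001 for both, adjusted 0.0011), and the other splits gave 77 to 1305. The gained count lay above all of these splits and the lost count below all of them. With lists of 1778 islands each, 108 regions were gained and 73 lost. Leaving out Epi-HOT-dL replicate 1 or 2 gave 12043 or 13354 gained and 119 or 122 lost regions, leaving out Epi-HOT replicate 1 gave 4964 and 1354, and leaving out Epi-HOT replicate 2 raised the lost regions to 2818. Kept regions rose from 56 to 95 or 1499 without Epi-HOT replicate 1 or 2.

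Epi-HOT-dP and Epi-HOT, which differ in the PRC2-interacting part, had few regions that both replicates shared. Of 14919 regions, 13106 (87.8%) had an island in a single library. There were 121 gained, 169 lost and 12 kept regions. Chromosome 13 carried 47 of the gained regions (38.8%) and 11 of the lost (6.51%), and chromosome 19 carried 0 and 2. The gained regions included chromosome 13 from 105473201 to 105481000, with FDRs of 6.79e-64 in Epi-HOT-dP replicate 1 and 1.37e-05 in replicate 2, and chromosome 8 from 130243201 to 130258000 (1.99e-107 and 3.99e-05), both within the stretches described above.

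Outside these stretches, the first gained region was at chromosome 17 from 54747601 to 54769600 (FDRs of 5.16e-07 and 5.29e-06), followed by chromosome 8 from 38742001 to 38756600 and chromosome 3 from 123547801 to 123555600. These last 3 were also called in both Epi-CTR libraries. The lost regions began with the same 3 as for Epi-HOT-dL, at chromosomes 13 (in the 90 to 110 Mb stretch), 1 and 2, and went on with chromosome 9 from 108003001 to 108008400, which both Epi-CTR and both Epi-HOT-dL libraries held. Of all 169 lost regions, 45.6% had an island in both Epi-CTR libraries and 20.7% in neither, and of the 121 gained, 12.4% and 59.5%.

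The gained and lost regions lay within the range of the other splits, which gave 37, 64, 109 and 1199, and above shifted positions (45.1 and 47.8; permutation p = 0.001, adjusted 0.0011). Their order depended on the setting. Without Epi-HOT-dP replicate 1 or 2, 6133 or 877 regions were gained against 180 or 199 lost. Without Epi-HOT replicate 1 or 2, 140 or 158 were gained against 1499 or 5208 lost. The 50% reciprocal overlap, which counted islands of replicate 1 rather than merged regions, gave 86 gained and 56 lost. Lists of 1116 islands each left 6 and 19. Epi-HOT replicate 1 and Epi-HOT-dP replicate 2, taken alone as an alternative added later, differed by 6239 gained and 5269 lost regions with 1254 kept.

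The deleted forms were also set against Epi-CTR, as secondary comparisons that share the Epi-CTR libraries with the first. Epi-HOT-dL had the most kept regions, 1951, with 1633 gained and 2406 lost, but kept counts also depend on the length of the lists. Epi-HOT-dP kept 46, with 93 gained and 4701 lost. Both Epi-HOT-dP libraries held only 191 regions in that comparison. Of the 93, 50 (53.8%) lay on chromosome 13, which held 32.0% of the islands of its replicate 1 and 3.68% of those of replicate 2. Without replicate 1 or 2 of the deleted form, Epi-HOT-dP kept 1970 or 115 regions and Epi-HOT-dL 3125 or 2595. Gains of Epi-HOT-dL were led by chromosome 17 from 77128601 to 77200600, with FDRs of 1.80e-06 and 6.70e-26, and by chromosome 11 from 1237801 to 1263800 (6.12e-11 and 3.23e-16). Epi-HOT replicate 1 had an island at both, but 75.9% of all gains had none in Epi-HOT. Losses of Epi-HOT-dL were led by chromosome 2 from 134574401 to 134584000, which Epi-HOT-dP also lost, and losses of Epi-HOT-dP by chromosome 11 from 69062401 to 69070200, with FDRs of 3.98e-56 and 3.90e-24 in the Epi-CTR replicates.

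Shifted positions gave 667 gained and 422 lost regions for Epi-HOT-dL and 36.5 and 781 for Epi-HOT-dP (permutation p = 0.001 for each count, adjusted 0.0011), and the other splits gave 727 to 1690 and 62 to 1787, so the gains of Epi-HOT-dL lay inside the range of its other splits and those of Epi-HOT-dP too. Leaving out an Epi-HOT-dL library turned the order, with 8348 gained and 3297 lost without replicate 1 and 10277 and 4156 without replicate 2. Without Epi-CTR replicate 1 or 2, Epi-HOT-dL lost 7399 or 9810 regions and gained 2683 or 2065. For Epi-HOT-dP, 3451 or 752 regions were gained without its replicate 1 or 2, and 11927 or 15629 were lost without Epi-CTR replicate 1 or 2.

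The regions that Epi-HOT lost were looked up in the deleted forms. Of the 4485, both Epi-HOT-dL libraries held 847 (18.9%, 95% interval 17.7 to 20.1), a single one 1810 and neither 1828, against 1.76% in both with shifted lists. Both Epi-HOT-dP libraries held 13 (0.290%, 0.154 to 0.495) and neither 3270 (72.9%). By library, 33.3% and 44.9% of the regions had an island in Epi-HOT-dL replicates 1 and 2, and 1.29% and 26.1% in Epi-HOT-dP replicates 1 and 2. Of the 1990 control regions that at least 1 Epi-HOT library held, both Epi-HOT-dL libraries held 867 (43.6%, 41.4 to 45.8), but the shares differed by width. Without and with an Epi-HOT island, they were 11.4% and 24.3% up to 4.8 kb, and 16.2% and 16.3% from 5 to 7.6 kb. They were 23.7% and 21.1% from 7.8 to 12.2 kb, and 35.3% and 65.0% from 12.4 kb on. Widths are those of the merged regions, so an Epi-HOT island widens the regions it meets. The width classes therefore do not compare Epi-CTR sites of like width, and cannot tell whether width accounts for the difference.

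If losses in Epi-HOT and in Epi-HOT-dL fell independently on the 6475 control regions, 1638 would be lost in both, and 1828 were; for Epi-HOT-dP, 3088 would be and 3270 were. The comparisons with Epi-CTR used the same 2 Epi-CTR libraries, which cannot be split further, so part of either excess may come from these shared controls. Regions that Epi-HOT held were also widened by its islands, with a median of 16.4 kb where replicate 1 alone held them. Where neither Epi-HOT library did, it was 6.4 kb. Wider regions meet other islands more easily, so neither excess shows that lines lost the same regions.

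**Figure D4:**
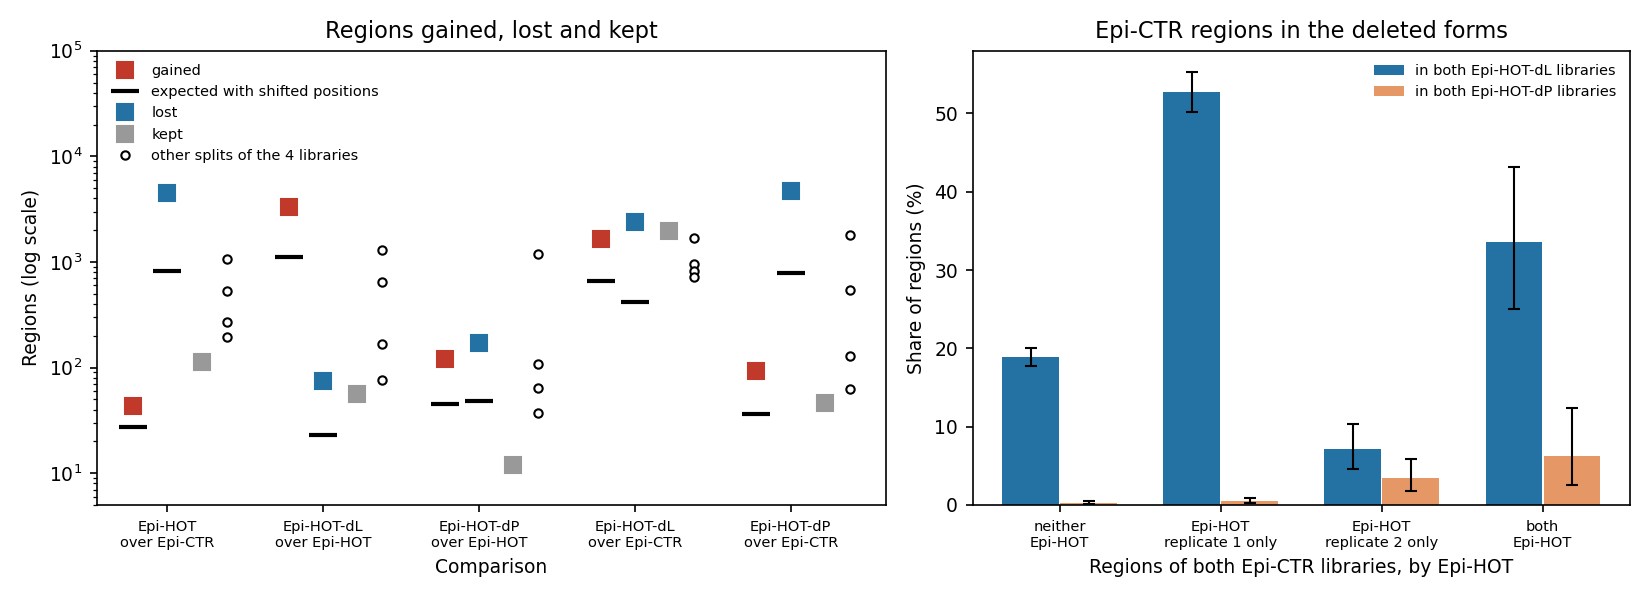
Left, regions gained, lost and kept in each comparison on a log scale, with dashes for the mean count after shifting 1 replicate and open circles for the other splits of the same 4 libraries. Right, share of the regions of both Epi-CTR libraries that also had an island in both Epi-HOT-dL or both Epi-HOT-dP libraries, in %, grouped by which Epi-HOT libraries held them, with exact 95% binomial intervals. It was 18.9% for Epi-HOT-dL where neither Epi-HOT library had an island and 52.7% where replicate 1 alone had it. These regions differed in median width (6.4 and 16.4 kb), which includes the Epi-HOT islands merged into them.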

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

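All tests of explanations in this part were chosen after the values had been seen. Each of 6 measures was searched for a library far from the rest, over all 8 libraries and over each of the 2 arms of 4, in 18 searches; 5 stood out, where chance alone gives about 1 in 20. Epi-HOT-dL replicate 2 accounted for 4 of them: it covered 203 Mb, far above the next library both over all 8 and among the Epi-CTR and Epi-HOT-dL libraries, and within that arm its median width of 7.6 kb and the 51.9% of its length in islands of 20 kb or more were far from the others. The fifth was the 32.0% of Epi-HOT-dP replicate 1 islands on chromosome 13, against 9.35% in the next library.

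The first pattern is the short lists of Epi-HOT replicate 2 and Epi-HOT-dP replicate 1, with many islands on chromosome 13 and few on chromosome 19. Only the strongest sites of a common set might have been called, but equally long lists of the smallest FDR from 5 other libraries held at least 7.35% and 7.28% of their islands on chromosome 19, against 0.394% and 0.359% in these, which argues against it for the lack of chromosome 19 islands. The overlap with Epi-CTR replicate 1, tried first and replaced after its outcome was seen, was mixed: 43.8% and 25.4% (22.9 to 28.1) of their islands met one, against 27.1% and 26.9% in equally long lists of Epi-HOT-dL replicate 1, but 51.0% to 65.9% and 51.4% to 73.0% in those of the 4 others. If the labels are right, the cell line as the whole cause is argued against by the other library of each line, whose chromosome 13 share was at most 3.68% (95% interval 3.28 to 4.11). This share, in Epi-HOT-dP replicate 2, was above the 1.99% to 2.51% of Epi-CTR and Epi-HOT-dL, so a smaller part may go with that line. Had the labels of Epi-HOT and Epi-HOT-dP been exchanged, both short lists would come from the same line and this argument would not hold. An exchange of labels between Epi-HOT and Epi-HOT-dP would raise the mean Jaccard index of both lines from 0.0127 to 0.0864. That rise cannot decide it, since the index depends on list length and an exchange pairs lists of more similar length. Epi-HOT replicate 1 also met Epi-HOT-dL replicate 2, of another line under either labelling, with a higher index (0.214). The test of resemblance within lines took the labels as given, so it cannot decide this either. Untested, and open as well, are a difference between cultures, a regional copy number difference and an Input from another culture.

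The second pattern is the wide islands of Epi-HOT replicate 1 and Epi-HOT-dL replicate 2, with 53.3% and 51.9% of their length in islands of 20 kb or more. The cell line as the whole cause is argued against by the other library of each line, with at most 6.75%. Several neighbouring sites joined into single islands is a candidate explanation: 63.3% (60.2 to 66.4) of the wide islands in Epi-HOT replicate 1 and 52.5% (50.6 to 54.4) of those in Epi-HOT-dL replicate 2 met 2 or more Epi-CTR sites, against 19.1% and 15.8% with shifted positions. A truly continuous signal over the same clusters would meet them too and stays open.

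The third pattern is the lower number of islands in the lines whose HOTAIR keeps the LSD1-interacting part. The short lists of Epi-HOT replicate 2 and Epi-HOT-dP replicate 1 are not the whole cause, as the other libraries of these lines had 6557 and 8079 islands, below the lowest of the other arm (14938). These other libraries covered 83.9 and 78.3 Mb, within the 77.3 to 203 Mb of the other arm. That leaves joining of sites into wider islands possible there but does not show it. Islands of Epi-HOT replicate 1 met 20.6% and 20.7% of the islands of Epi-CTR replicates 1 and 2. Those of Epi-HOT-dP replicate 2 met 22.8% and 19.1%. In the other arm, islands of Epi-HOT-dL replicate 1 met 25.1% and 28.0%, and those of Epi-HOT-dL replicate 2 met 42.9% and 38.4%. Most Epi-CTR islands thus stayed unmet in the other arm too, so these shares cannot bound how much joining contributes. Joining cannot account for the short lists, which covered at most 15.6 Mb. Sequencing depth or yield of the immunoprecipitation cannot be told apart from the lines, since 0 of the lists give reads per island. The form of HOTAIR, the biological difference that the design names, stays open too, because the smallest p with 4 lines is 0.333.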

How the results depend on the processing

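An FDR limit of 0.001 left the test of the number of islands between arms at an exact permutation p of 0.0286 (4.03 times against 5.27), and the test of resemblance within lines stayed above the threshold under its 4 alternatives (exact p = 0.162 to 0.410); the 2 measures other than the Jaccard index were added after seeing the data. In the main setting the number of islands passed the threshold only before adjustment over 3 measures (exact permutation p = 0.0286, adjusted 0.0857). Even unadjusted it passed no longer with an FDR limit of 1e-05 (2.92 times, exact permutation p = 0.143), with regroupings restricted to a replicate block (the difference unchanged, 0.0556, the smallest its 36 regroupings allow) or without Epi-HOT replicate 2 and Epi-HOT-dP replicate 1 (2.32 times, 0.0667, the smallest of 15). All 3 settings were added after seeing the data. Leaving out single libraries gave an unadjusted 0.0286 to 0.0857. Same-numbered libraries of different lines had a mean Jaccard index of 0.0656, the others 0.0860, which gives no sign of pairing by replicate number. The index also depends on list length and the difference was not tested, so such pairing is not excluded. Region counts match no library to another, so pairing would leave them as they are.

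Counts of regions mostly fell with stricter settings; merging within 1 kb moved no count by over 1.5 times. With an FDR limit of 0.001, gained and lost regions were 9 and 1822 for Epi-HOT over Epi-CTR, 499 and 28 for Epi-HOT-dL over Epi-HOT, 29 and 30 for Epi-HOT-dP over Epi-HOT, 250 and 1263 for Epi-HOT-dL over Epi-CTR, and 27 and 1920 for Epi-HOT-dP over Epi-CTR. Lists of equal length gave 65 and 286 for Epi-HOT over Epi-CTR, 108 gained for Epi-HOT-dL over Epi-HOT, 6 and 19 for Epi-HOT-dP over Epi-HOT, and 7 and 244 for Epi-HOT-dP over Epi-CTR. The 50% reciprocal overlap counted islands of replicate 1 rather than merged regions. They had to share at least 50% of both widths with an island of replicate 2 and with none of the other line. An island met by a much wider one of the other line still counted, so absence was defined more loosely. With this setting, 26 were gained for Epi-HOT over Epi-CTR, 1179 gained and 38 lost for Epi-HOT-dL over Epi-HOT, 56 lost for Epi-HOT-dP over Epi-HOT and 910 gained for Epi-HOT-dL over Epi-CTR. Losses of Epi-HOT-dL over Epi-CTR rose from 2406 to 2732. Epi-HOT replicate 1 and Epi-HOT-dP replicate 2 alone, added after seeing the data, gave 6239 and 5269.

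Leaving out single libraries, which loosens what both replicates must show, gave 64 to 3163 gained and 4831 to 15652 lost for Epi-HOT over Epi-CTR, 3345 to 13354 and 119 to 2818 for Epi-HOT-dL over Epi-HOT, 140 to 6133 and 180 to 5208 for Epi-HOT-dP over Epi-HOT, 2065 to 10277 and 3297 to 9810 for Epi-HOT-dL over Epi-CTR, and 109 to 3451 and 4773 to 15629 for Epi-HOT-dP over Epi-CTR. Which of gained and lost was larger turned only for Epi-HOT-dP over Epi-HOT (reciprocal overlap, either Epi-HOT-dP library left out, or the added pair) and Epi-HOT-dL over Epi-CTR (either Epi-HOT-dL library left out); the cause was not tested. Alternatives that needed reads or promoters were not run. Depth is unknown and limits every count of regions without an island.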

Other observations

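The test of the hypothesis in this part was chosen after the values had been seen, and its reference was changed afterwards from all control regions to those that Epi-HOT held. Wide islands and the chromosome 13 libraries marked different parts of the genome. Epi-HOT replicate 1 had 962 islands of 20 kb or more, which covered 44.7 Mb. They were met by 2066 islands of Epi-CTR replicate 1, 3.81 times as many as with shifted positions, and by 1215 of Epi-HOT-dP replicate 2, 4.67 times as many. Islands of Epi-HOT replicate 2 and Epi-HOT-dP replicate 1 met them 8 and 4 times, or 0.342 and 0.283 times the shifted number. The wide islands of Epi-HOT-dL replicate 2 showed the same order, with 3.65 times for Epi-CTR replicate 1 and 0.209 and 0.0269 times for Epi-HOT replicate 2 and Epi-HOT-dP replicate 1.

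Which Epi-HOT library held a control region went with where the region lay. Regions of both Epi-CTR libraries that Epi-HOT replicate 1 alone held numbered 1525, with a median width of 16.4 kb, 10.2% on chromosome 19 and 52.7% (95% interval 50.2 to 55.3) found in both Epi-HOT-dL libraries. The 352 that Epi-HOT replicate 2 alone held had a median width of 8.6 kb, 0.284% on chromosome 19 and 7.10% (4.65 to 10.3) in both Epi-HOT-dL libraries. Both sets were merged with the Epi-HOT islands that met them. Their widths and the Epi-HOT-dL islands found in them are therefore those of the merged stretch, not of the Epi-CTR sites alone.

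The hypothesis that control regions missing from Epi-HOT are called again when the LSD1-interacting part is removed could not be decided. Of the 4485 regions, 18.9% (17.7 to 20.1) had an island in both Epi-HOT-dL libraries, above the 1.76% with shifted positions and below the 43.6% (41.4 to 45.8) of control regions that Epi-HOT held. The latter were merged with the Epi-HOT islands that met them. Regions held by Epi-HOT would be found in Epi-HOT-dL under the hypothesis and without it, so a lower share among the missing ones cannot count against it, and a share above shifted positions also arises where calling alone differs between libraries.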
